A study of Solanum lycopersicum with 12 samples.

How the data were processed

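Leaves of wild-type tomato seedlings were sampled after 7 days of treatment, and polyadenylated RNA was sequenced in 12 libraries, 3 in each of 4 groups. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a VAHTS Universal V6 kit. The groups were untreated plants (CK), plants under cadmium (Cd), plants under cadmium given indole-3-acetic acid (Cd+IAA), and a further group whose labels conflict. That group is called by its library name, MT-Cd. Its treatment field (Cd+WT) and its title (WT-Cd) name it differently, and the series' design text does not list it. These labels all name cadmium, but what else, if anything, those plants received is left open here.

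The authors deposited a single table of FPKM values (fragments per kilobase of gene model, relative to the library's total), with 1 column per library and 23989 genes. Gene length and sequencing depth are therefore already divided out. The aligner, counting tool, genome build and annotation are not given in the sources used here. All 12 value columns were matched to a library by name. No read counts were used. Relative depth was read from low genes, whose values fall on repeated steps: 92.5% of 4674 such values were whole multiples of the step within a tolerance of 0.05. On that scale the libraries lay between 0.803 (CK replicate 1) and 1.0 (Cd replicate 1), so no library was much shallower than the rest, while the absolute depth remained unknown and no counting intervals are given. Column sums ran from 690220 to 719783 FPKM. No pair of libraries held the same values.

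Gene names come from the table itself, which holds 1309 symbols and 22680 LOC numbers, and from a RefSeq gene table of assembly SLM_r2.1 used only for names. It matched 22804 identifiers and gave a symbol to 504 LOC numbers, so 1813 genes had a name. No coordinates are given, because the build behind the FPKM values is not known. Genes with near-identical copies (light-harvesting, chitinase and other families) share reads, and how these were divided is not known, so values of single family members are uncertain.

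Genes with at least 1 FPKM in at least 3 libraries were tested (17156 genes). Values were transformed to log2(FPKM + 1) and fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 12 libraries (8 residual degrees of freedom) and a variance trend. All 6 comparisons between groups were taken from that fit, two-sided, with Benjamini-Hochberg adjustment over genes within a comparison and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and are given with their standard errors. Levels are given as mean ± SD over 3 libraries. Nothing in the labels says that replicates came from separate plants, so p-values measure only the spread between these samples, which may be technical.

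The gene lists planned before the data were examined relied on gene descriptions and Solyc identifiers, and matched 0 genes of this table. They were replaced by 29 lists of symbols (503 symbols), drawn up after the identifiers, library totals and correlations between libraries had been seen and before any comparison. Lists with at least 4 tested members (26 lists) were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the lists of a comparison. An estimated correlation and limma's fry were the alternatives. Where the members of a list are counted, the count is of those past the threshold over all genes tested, with the count adjusted over the list alone where it differs. COMT1, which the series' title names, is not analysed here, because no symbol of the table identifies it.

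Genes were named by a rule fixed before the data were examined: for Cd against CK, Cd+IAA against Cd and MT-Cd against Cd, the 5 highest and 5 lowest fold changes past the threshold with a mean of at least 5 FPKM and no overlap between groups, up to 3 members per list with the smallest p (or 1 where none passed), and 6 genes moved in opposite directions by Cd and by IAA; for the other comparisons, 3 each way. Where the rule asked for a description, a symbol other than a LOC number was required instead, a change made before the comparisons. The text gives the members that matter from this set.

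The procedure was tested on simulated data for Cd against CK over 17156 genes. It recovered 37.3% of the genes shifted by 0.5 on the log2 scale, 91.0% of those shifted by 1 and 97.0% of those shifted by 2, with 6 false calls. The shifted genes were drawn only from those with a mean log2(FPKM + 1) above that of 5 FPKM. Recovery among lower genes was therefore not tested. For Cd+IAA against Cd a list of 23 genes shifted by 0.5 was recovered, with 1 other list of 26 called. Genes were drawn independently of each other in these simulations. They therefore say nothing about camera on lists whose members vary together (estimated correlation 0.646 for that list in the data). Alternatives were another pseudocount, other filters, rescaling to a common total, quantile normalization, a fit of only the 6 libraries compared, a replicate block, no variance trend, library weights, a minimum fold change of 2, and each library left out in turn. Median-ratio scaling, and leaving out both Cd+IAA replicate 1 and MT-Cd replicate 3, were added after seeing the data. Under median-ratio scaling the libraries are divided by their median ratio to the genes' geometric means.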

Results

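Gene expression was measured in 12 leaf libraries of wild-type tomato, 3 each from untreated plants (CK), plants under cadmium (Cd), plants under cadmium given the auxin indole-3-acetic acid (Cd+IAA) and the group named MT-Cd, all after 7 days. The series asks how auxin bears on tolerance to cadmium, a toxic metal, and whether melatonin synthesis takes part. The first principal component of the 17156 genes tested held 49.1% of the variance and set the CK libraries (scores -53.1 to -47.5) apart from the other 9 (-3.3 to 50). The second held 17.3% and set Cd (13.2 to 33.4) apart from Cd+IAA (-36.2 to -11). Cd+IAA replicate 1 scored 50 on the first component, against 8.6 and 4.2 in replicates 2 and 3. MT-Cd replicate 3 scored 34.3, against -3.3 and 7.8.

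**Figure D1:**
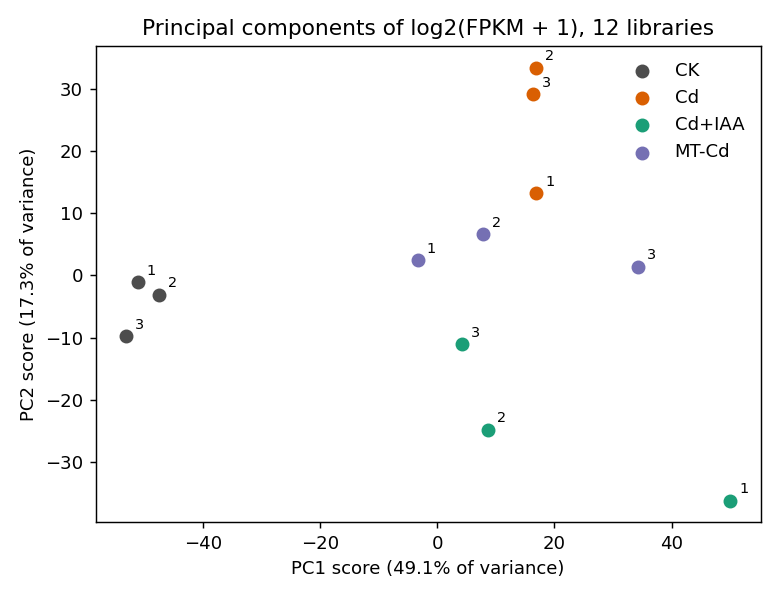
Scores of the 12 libraries on the first (x axis, 49.1% of the variance) and second (y axis, 17.3%) principal components of log2(FPKM + 1), 1 point per library, coloured by group and numbered by replicate. The CK libraries lie at -53.1 to -47.5 on the first component, and Cd+IAA replicate 1 lies at 50.

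Under cadmium, leaves held more transcript of most defence protein genes tested and less of most light-harvesting and photosystem genes. TPM-1 rose from 7.31 ± 1.81 FPKM in CK to 1092 ± 257 in Cd (SD, n = 3), a log2 fold change of 7.04 ± 0.43 (SE; limma adjusted p = 1.7e-05). The chitinase gene CHI9 rose to 991 ± 534 FPKM (log2 fold change 5.61 ± 0.41), and the chitinase gene CHI3 from 14.1 ± 2.2 to 350 ± 61.9 FPKM (4.53 ± 0.45). NP24, an osmotin-like protein gene, rose by 5.88 ± 0.54 and P4, a pathogenesis-related gene, by 5.47 ± 0.76 on the log2 scale. SODCP.2 and SODCC.1, which encode copper/zinc superoxide dismutases, fell to 10.7 ± 1.75 and 41.9 ± 9.61 FPKM, from 219 ± 112 and 179 ± 21.8 in CK. Each of these genes lay, in all 3 Cd libraries, outside the range of the CK libraries. Lack of overlap was a condition for naming the highest and lowest genes, so it adds no support.

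Of 22 tested genes for pathogenesis-related proteins, 15 rose under cadmium, 0 fell and 7 did not pass the test (16 rose when adjusted over the list alone). The list stood above the other genes (camera adjusted p = 0.000217), but adjusted p = 0.617 with an estimated correlation. Of 34 ethylene synthesis and signalling genes 26 rose and 0 fell (28 rose when adjusted over the list alone; camera adjusted p = 0.000152; adjusted p = 0.718 with an estimated correlation). Among them ACO4, an ethylene-forming oxidase gene, rose by 1.57 ± 0.16 and EIL4, a gene of ethylene signalling, by 0.81 ± 0.11 on the log2 scale. After median-ratio scaling 16 of the 34 still rose. Of 21 jasmonate and wounding genes 11 rose (camera adjusted p = 0.0299; adjusted p = 0.718 with an estimated correlation), among them LAPA1, a leucine aminopeptidase gene (2.90 ± 0.39), and opr3, a jasmonate synthesis gene (0.82 ± 0.11). The jasmonate call was lost without CK replicate 2 (adjusted p = 0.148) and without Cd replicate 1 (0.0575).

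Of 23 photosystem and light-harvesting genes 17 fell and 0 rose under cadmium (19 fell and 1 rose when adjusted over the list alone; camera adjusted p = 4.26e-16; adjusted p = 0.548 with an estimated correlation). CAB7, a light-harvesting protein gene, fell from 5406 ± 353 to 2980 ± 359 FPKM (log2 fold change -0.86 ± 0.14, limma adjusted p = 0.00148), and PETE, the plastocyanin gene, from 3914 ± 82.8 to 1999 ± 243 FPKM. CAB5 had a log2 fold change of -1.40 ± 0.27. That of CAB12 was -1.91 ± 0.60 (limma adjusted p = 0.0289), a call lost without CK replicate 1, 2 or 3 or Cd replicate 1 or 2 (adjusted p up to 0.0845). After quantile normalization 3 of the 23 genes fell, 0 rose and the list did not pass (camera adjusted p = 0.0893). Of 17 chlorophyll and carotenoid synthesis genes 5 fell, POR2 of chlorophyll synthesis among them (-0.79 ± 0.15), and 1 rose, CrtR-b2 of carotenoid synthesis (1.95 ± 0.42; camera adjusted p = 0.000152; adjusted p = 0.487 with an estimated correlation), against 11 and 1 after median-ratio scaling.

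Among 12 metal transport and chelation genes 5 rose and 2 fell (6 and 2 when adjusted over the list alone; camera adjusted p = 0.848). NRAMP3, a metal transporter gene, rose from 32.0 ± 0.811 to 104 ± 23.6 FPKM (1.64 ± 0.23), FRO1, a ferric reductase gene, by 1.62 ± 0.20 and CCH, a copper chaperone gene, by 1.26 ± 0.14. In the list for reactive oxygen scavenging 8 of 26 genes rose and 5 fell, against 4 and 10 after median-ratio scaling (8 and 6 when adjusted over the list alone; camera adjusted p = 0.0395, downward; adjusted p = 0.718 with an estimated correlation), while the list's median was 0.08 and its mean -0.13. GPXle-2, a glutathione peroxidase gene, rose by 1.07 ± 0.13. That call of the list was lost without CK replicate 3 (adjusted p = 0.0514), Cd replicate 1 (0.0575) or Cd replicate 3 (0.0576). Of 37 cell wall genes 6 rose and 2 fell (3 and 2 when adjusted over the list alone), against 2 and 4 after median-ratio scaling, with a downward call (camera adjusted p = 0.0395; adjusted p = 0.754 with an estimated correlation, 0.495 after median-ratio scaling, 0.139 without Cd replicate 1 and 0.050 without CK replicate 1). The list's median was 0.05 and its mean 0.03. All 3 tested members of the glutathione S-transferase list that passed rose, of 4 tested, led by GST-T4 (2.71 ± 0.45; camera adjusted p = 0.263).

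In all, 6762 of 17156 genes differed between Cd and CK, 5982 higher and 780 lower in Cd (88.5% higher), and 920 of them by at least 2-fold. The median log2 fold change of all tested genes was 0.22, and the 100 most abundant genes held 32.3 ± 1.09% of the FPKM sum in Cd against 40.04 ± 1.57% in CK (SD, n = 3). After median-ratio scaling, which removes that shift, 4464 genes differed, 2247 higher and 2217 lower (50.3% higher), and 3027 genes had the same call under both scalings. The count was 4294 without CK replicate 3 and 4376 without CK replicate 1.

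**Figure D2:**
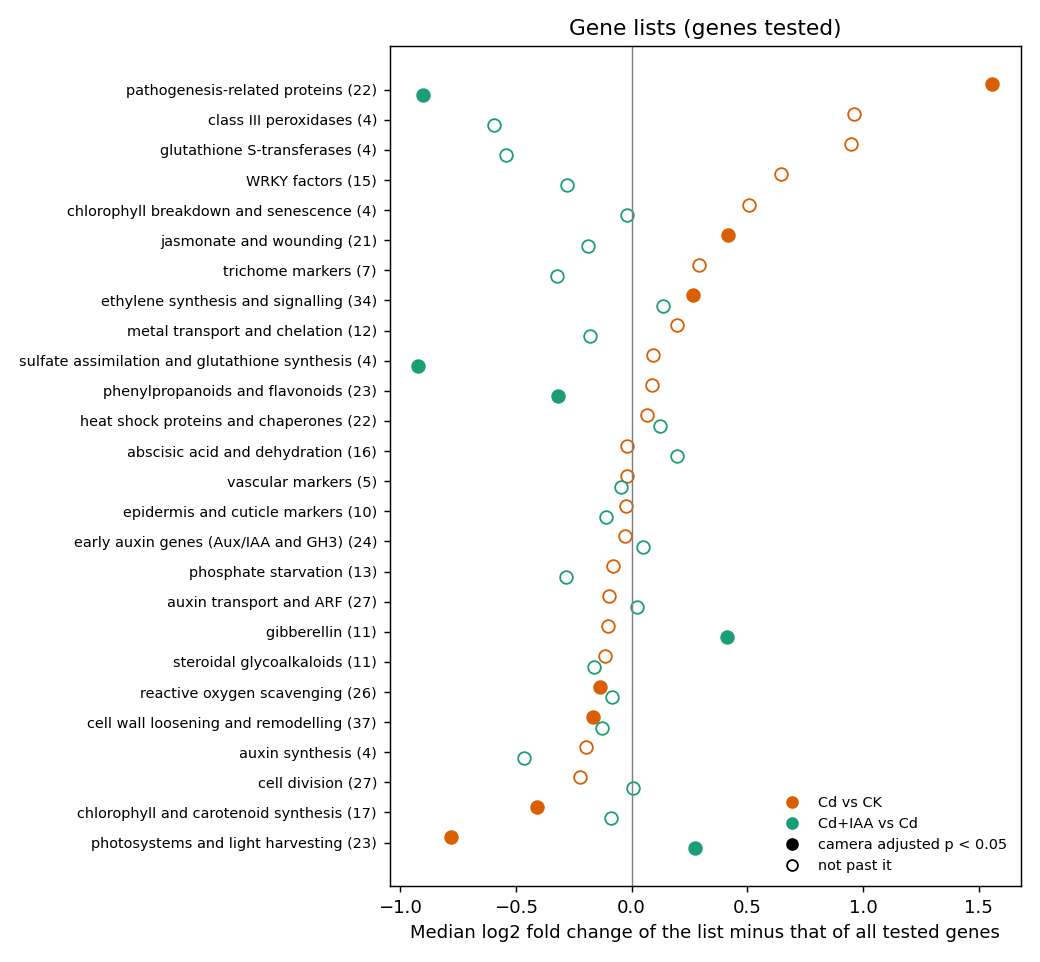
Median log2 fold change of each gene list minus that of all tested genes (x axis), for Cd against CK and for Cd+IAA against Cd, with the number of genes tested in brackets and filled points where camera passed an adjusted p of 0.05 at its preset correlation. Pathogenesis-related proteins stand at 1.56 for Cd against CK, and photosystem genes at -0.78.

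Adding indole-3-acetic acid under cadmium was compared with cadmium alone, to see what auxin changed in stressed leaves. Some auxin-inducible genes rose: GH3-15 (LOC101264094), of the auxin-conjugating GH3 family, went from 3.51 ± 0.937 FPKM in Cd to 21.3 ± 8.62 in Cd+IAA (SD, n = 3; log2 fold change 2.24 ± 0.25; limma adjusted p = 0.00131). IAA5, an Aux/IAA repressor gene, went from 1.48 ± 0.182 to 9.05 ± 1.29 FPKM (2.02 ± 0.18; adjusted p = 0.00058 by limma). Of 24 Aux/IAA and GH3 genes 6 rose and 0 fell, against 5 and 1 after median-ratio scaling (7 and 2 when adjusted over the list alone). The list as a whole did not pass camera (camera adjusted p = 0.0567, and 0.702 with an estimated correlation). By fry, which asks whether a list's own genes move 1 way, it passed upward (fry adjusted p = 0.0343). ARF10, an auxin response factor gene, rose by 0.53 ± 0.08, while FZY6, of auxin synthesis, had a log2 fold change of -1.16 ± 0.17. TAS14, a dehydrin gene, rose by 4.098 ± 0.73 and Asr4, named for abscisic acid, stress and ripening, by 1.62 ± 0.18. The log2 fold change of CYP707A2 (LOC101249565), an abscisic acid hydroxylase gene, was -2.31 ± 0.30.

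Some of the defence genes that were high in Cd were lower in Cd+IAA. CHI9 stood at 98.6 ± 27.2 FPKM in Cd+IAA against 991 ± 534 in Cd (log2 fold change -3.22 ± 0.41; limma adjusted p = 0.00228), TPM-1 at 152 ± 103 against 1092 ± 257 (-3.01 ± 0.43) and NP24 at 9.41 ± 9.01 against 111 ± 58.6 (-3.65 ± 0.54). Of the 22 pathogenesis-related genes 5 fell and 0 rose (12 and 1 when adjusted over the list alone; camera adjusted p = 6.28e-05; adjusted p = 0.552 with an estimated correlation). Of 4 sulfate assimilation and glutathione synthesis genes 3 fell (camera adjusted p = 0.000404; adjusted p = 0.467 with an estimated correlation): GSH2, of glutathione synthesis, from 31.4 ± 2.55 to 18.1 ± 1.4 FPKM (-0.76 ± 0.08), and the sulfate transporter genes ST4.1 (-1.13 ± 0.16) and ST2 (-1.06 ± 0.16). Of 23 phenylpropanoid and flavonoid genes 3 fell, led by PAL2 (-1.28 ± 0.23; 6 fell when adjusted over the list alone; camera adjusted p = 0.00335; adjusted p = 0.702 with an estimated correlation). Of 26 reactive oxygen scavenging genes 3 fell, GME2 and GME1 of ascorbate synthesis (by 0.61 and 0.77 on the log2 scale) and AFRR, and 1 rose (2 when adjusted over the list alone; camera adjusted p = 0.226). The gene that rose, named after its value was seen, was SODCC.1 (1.096 ± 0.275; limma adjusted p = 0.0326). AFRR lost its call without Cd replicate 2 or 3 or Cd+IAA replicate 2, and SODCC.1 without those or Cd+IAA replicate 1 (adjusted p up to 0.125). Of 12 metal transport and chelation genes 5 fell and 1 rose (camera adjusted p = 0.164, and 0.702 with an estimated correlation). NRAMP3, FRO1 and CCH, named above for their rise under cadmium, were lower in Cd+IAA than in Cd. Their log2 fold changes were -0.992 ± 0.228, -0.817 ± 0.195 and -0.55 ± 0.139 (limma adjusted p = 0.0238, 0.0279 and 0.0336).

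Of 11 gibberellin genes 2 rose, 3OH-1 (1.62 ± 0.20) and SlGID2 (0.43 ± 0.12; limma adjusted p = 0.0435, and up to 0.122 with any of the 6 libraries left out), with 4 higher when adjusted over the list alone and a list call of camera adjusted p = 0.00868 and adjusted p = 0.552 with an estimated correlation. Photosystem genes stood above the other genes as a list (camera adjusted p = 0.00868; adjusted p = 0.865 with an estimated correlation), with 2 of 23 called, CAB7 and PSBR (6 and 1 lower when adjusted over the list alone), and 0 called after median-ratio scaling (camera adjusted p = 0.0511). That list call was also lost without Cd replicate 2 (adjusted p = 0.0693), Cd+IAA replicate 2 (0.21) or Cd+IAA replicate 3 (0.132). PSBR lost its call with any of the 6 libraries left out (adjusted p up to 0.158), and CAB7 without Cd replicate 2 or Cd+IAA replicate 2 or 3 (up to 0.0842).

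In all, 1570 genes differed between Cd+IAA and Cd, 649 higher and 921 lower, 346 of them by at least 2-fold. Quantile normalization turned the balance, with 2065 genes, 1150 higher and 915 lower, while median-ratio scaling gave 1773, 705 higher and 1068 lower. The count was 559 without Cd replicate 2, 705 without Cd replicate 3, 745 without Cd+IAA replicate 2, 1029 without Cd replicate 1 and 474 in a fit of only these 6 libraries.

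Genes changed by cadmium and moved the other way in Cd+IAA numbered 557, of which 435 were higher and 122 lower in Cd than in CK. After median-ratio scaling these were 355 and 227, and after quantile normalization 296 and 346. In the main fit independent lists as long as those of the 2 comparisons would share 321.1 and 29.5 genes, while unchanged groups sharing the Cd libraries gave 0 such genes in each of 100 simulated draws, which hold hardly any calls to share and so say nothing about the excess. Across the 17156 genes, which are not independent replicates, the fold changes of the 2 comparisons correlated at r = -0.31 (simulated mean -0.50). Their covariance was -0.0627, against -0.0180 in the simulation, which drew each gene independently of the others. The Cd libraries are too few to split, and part of the excess over independent lists can come from sharing them. Of the 557 genes 390 did not pass the threshold between Cd+IAA and CK, 122 still differed in the direction of cadmium and 45 in the other. Not passing does not show a return to the CK level. CHI9, pip1 and TPM-1 still stood above CK, by 2.38 ± 0.41, 1.98 ± 0.30 and 4.03 ± 0.43 on the log2 scale, though the Cd+IAA to Cd call of pip1 was lost without Cd replicate 3 or Cd+IAA replicate 2 (adjusted p up to 0.0599). ER1 stood at 1.3 ± 1.18 FPKM in Cd+IAA and 0.609 ± 0.32 in CK, after 18.6 ± 10.3 in Cd, and its Cd+IAA to CK difference did not pass (limma adjusted p = 0.404). A larger number, 6072 of the 6762 genes called under cadmium, did not pass the threshold between Cd+IAA and Cd, and 133 moved further in the direction of cadmium, 92 higher and 41 lower. The count of 557 was 370 without CK replicate 3, 185 without Cd replicate 2, 243 without Cd replicate 3 and 238 without Cd+IAA replicate 2, and 1184 without both libraries that lay apart.

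**Figure D3:**
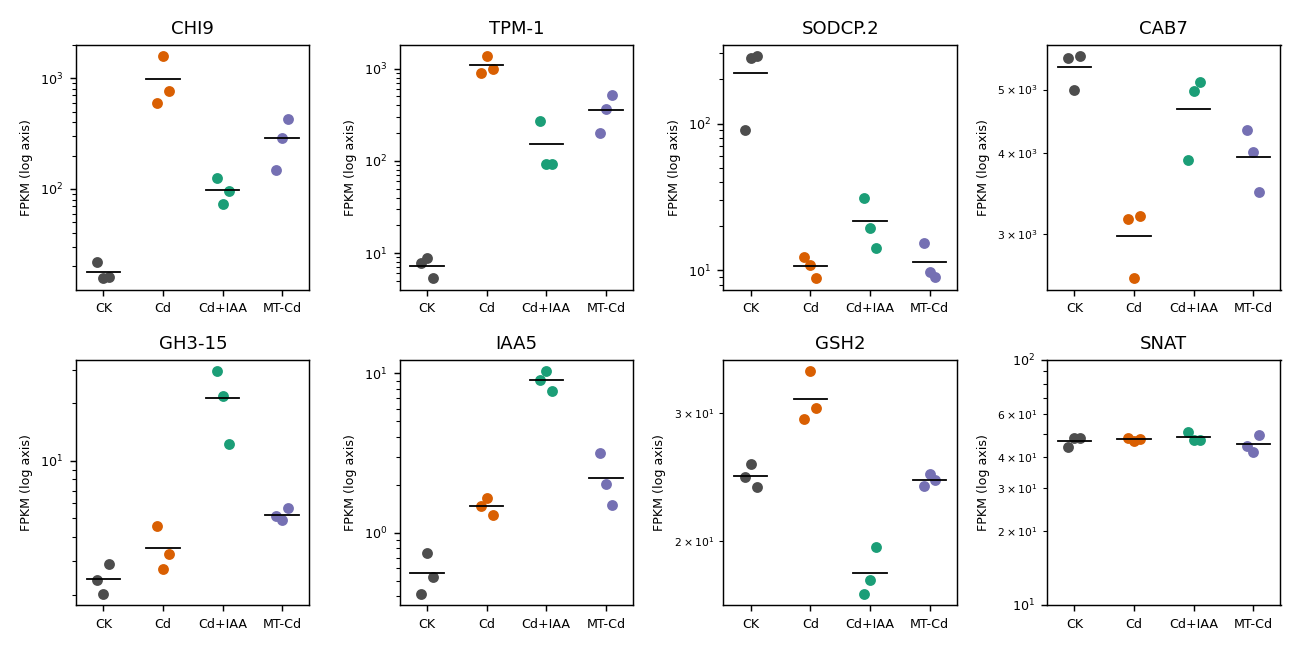
FPKM (y axes, log scale) of 8 genes in the 12 libraries, 1 point per library and a line at each group's mean. CHI9 averaged 991 FPKM in Cd and 98.6 in Cd+IAA, and SNAT lay near 46.6 FPKM in CK and 48.5 in Cd+IAA.

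Cd+IAA and CK differed at 8832 genes, 7247 higher and 1585 lower in Cd+IAA (82.1% higher; 6121 genes, 47.5% higher, after median-ratio scaling; median log2 fold change 0.25). TAS14 (4.24 ± 0.73), PR-5 (4.12 ± 0.71) and TPM-1 rose most among named genes, and SODCP.2 (-3.18 ± 0.41), TCP17 (-2.32 ± 0.25) and tXET-B2 (-2.21 ± 0.46) fell most. Ethylene genes (29 of 34 higher, 2 lower; camera adjusted p = 0.000182; adjusted p = 0.783 with an estimated correlation) stood above the other genes. Photosystem genes (3 of 23 lower, 2 when adjusted over the list alone and 10 after median-ratio scaling; camera adjusted p = 4.8e-07; adjusted p = 0.783 with an estimated correlation and 0.297 after quantile normalization) stood below them. Camera called 8 lists here, 7 of them downward, and 0 with an estimated correlation. Chlorophyll and carotenoid synthesis (0 higher and 4 lower of 17, camera adjusted p = 0.000264) and reactive oxygen scavenging (5 higher and 6 lower of 26, 0.00443) were among the downward ones. The rest were cell wall, phenylpropanoid, steroidal glycoalkaloid, and sulfate and glutathione synthesis genes (0.014 to 0.0415), each lost without at least 1 library.

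Melatonin synthesis was represented by SNAT (LOC101262573), serotonin N-acetyltransferase. It stood at 46.6 ± 2.27 FPKM in CK, 47.4 ± 0.642 in Cd, 48.5 ± 2.08 in Cd+IAA and 45.4 ± 3.79 in MT-Cd (SD, n = 3), and no comparison passed the threshold by limma. Relative to the median shift it was lower than in CK: after median-ratio scaling its log2 fold change was -0.23 in Cd (limma adjusted p = 0.0213), -0.23 in Cd+IAA (limma adjusted p = 0.0181) and -0.27 in MT-Cd (limma adjusted p = 0.0143).

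Between MT-Cd and Cd 79 genes differed, 9 higher and 70 lower in MT-Cd. LAPA1 stood at 3.91 ± 1.96 FPKM in MT-Cd against 20.2 ± 6.28 in Cd (log2 fold change -2.14 ± 0.39; limma adjusted p = 0.0431), ME2 at 23.9 ± 5.54 against 65.1 ± 4.59 and CYP707A2 at 1.052 ± 0.402 against 6.26 ± 1.25. ARF10 stood at 7.58 ± 0.373 against 5.18 ± 0.303 FPKM. Pathogenesis-related genes stood below the other genes (2 of 22 lower, 9 when adjusted over the list alone; camera adjusted p = 0.000117; adjusted p = 0.678 with an estimated correlation). Camera also put photosystem (adjusted p = 0.0212), gibberellin (0.0323) and chlorophyll and carotenoid synthesis genes (0.0363) above the other genes, with 0 members called. Sulfate and glutathione synthesis genes stood below them (0.0363, 1 member called). Each of these further calls was lost without any 1 of at least 2 libraries, and with an estimated correlation (camera adjusted p of at least 0.678). The count of calls fell with any of the 6 libraries left out. Without MT-Cd replicate 1 limma called 0 genes, with 1874 at an unadjusted p under 0.05 against 2204 in the main fit. Without Cd replicate 3, Cd replicate 2, MT-Cd replicate 3, MT-Cd replicate 2 or Cd replicate 1 it called 3, 5, 8, 27 or 28. Cd+IAA replicate 1 enters this comparison only through the shared estimate of the spread. Leaving it out raised the count to at least 195, the number then shared with Cd+IAA against Cd. LAPA1, CYP707A2 and ARF10 lost their calls with any of the 6 libraries left out (adjusted p up to 0.170), and ME2 with 5 of them (up to 0.129, without MT-Cd replicate 1).

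Of the 79 genes 74 also differed between Cd+IAA and Cd in the same direction, 8 higher and 66 lower. Independent lists would share 0.3 and 3.8 genes, while the simulation of unchanged groups, with hardly any calls to share, gave at most 1 and says nothing about the excess. The fold changes correlated across genes at r = 0.64 (simulated mean 0.50), with a covariance of 0.0692 against 0.0180 simulated with genes drawn independently. Both comparisons use the same Cd libraries, which are too few to split, so part of the excess can come from them. The count was 195 without Cd+IAA replicate 1 and 0 without MT-Cd replicate 1, and 3, 5, 7, 26, 27, 34 and 35 without Cd replicate 3, Cd replicate 2, MT-Cd replicate 3, MT-Cd replicate 2, Cd replicate 1, Cd+IAA replicate 2 and Cd+IAA replicate 3.

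Compared directly, MT-Cd and Cd+IAA differed at 91 genes, 51 higher and 40 lower in MT-Cd. GH3-15 stood at 5.23 ± 0.398 FPKM in MT-Cd against 21.3 ± 8.62 in Cd+IAA (-1.76 ± 0.25; limma adjusted p = 0.0189) and IAA19 (LOC101055549), an Aux/IAA gene, at 8.52 ± 1.63 against 23.2 ± 7.0. ST4.1 (0.96 ± 0.16) and NR, an ethylene receptor gene (0.93 ± 0.16), were higher. GH3-15 and IAA19 lost their calls without Cd+IAA replicate 2 or MT-Cd replicate 1, 2 or 3 (adjusted p up to 0.0943), and ST4.1 and NR without each library but Cd+IAA replicate 3 (up to 0.102). The count was 280 without Cd+IAA replicate 3, 49 without Cd+IAA replicate 1, 10 without Cd+IAA replicate 2, and 10, 12 and 26 without MT-Cd replicates 1, 2 and 3.

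MT-Cd and CK differed at 6465 genes, 5480 higher and 985 lower in MT-Cd (84.8% higher; 3954 genes, 48.1% higher, after median-ratio scaling; median log2 fold change 0.20). TPM-1 (5.36 ± 0.43), P4 (4.42 ± 0.76) and CHI9 (3.83 ± 0.41) rose most among named genes, and SODCP.2 (-4.02 ± 0.41), ca2 (-2.93 ± 0.57) and SD1 (-2.22 ± 0.17) fell most. The count was 3203 without MT-Cd replicate 3, 3810 without CK replicate 1 and 3841 without CK replicate 3.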

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

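Median-ratio scaling and the joint omission of Cd+IAA replicate 1 and MT-Cd replicate 3 were chosen after the data were seen. Where a value moved below, the cause was not tested unless stated. Counts of genes were at least 920 for Cd against CK, 1108 for Cd+IAA against CK, 731 for MT-Cd against CK and 346 for Cd+IAA against Cd, each of these under a minimum fold change of 2, while counts involving MT-Cd against Cd or Cd+IAA rested on few calls and moved under most settings. The absolute depth of the libraries is unknown, which leaves the precision of low genes open.

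The main counts were 6762 genes (Cd against CK), 1570 (Cd+IAA against Cd), 8832 (Cd+IAA against CK), 79 (MT-Cd against Cd), 91 (MT-Cd against Cd+IAA), 6465 (MT-Cd against CK), 557 moved back and 74 shared. A pseudocount of 0.1 gave 12 genes for MT-Cd against Cd and 12 shared. Without a filter on low values these were 30 and 29, with 60 for MT-Cd against Cd+IAA, in a test over more genes. With a mean of at least 5 FPKM they were 52 and 49, and after rescaling to a common total 48 and 46. Quantile normalization gave 4358 for Cd against CK, 5797 for Cd+IAA against CK, 3674 for MT-Cd against CK and 139 for MT-Cd against Cd+IAA. Median-ratio scaling gave 4464 for Cd against CK and 3954 for MT-Cd against CK. Library weights gave 4530 for Cd+IAA against Cd, 1213 for MT-Cd against Cd, 2023 for MT-Cd against Cd+IAA, 2153 moved back and 947 shared. Fitting only the libraries compared gave 474 for Cd+IAA against Cd, 21 for MT-Cd against Cd, 1 for MT-Cd against Cd+IAA, 184 moved back and 12 shared, with fewer residual degrees of freedom. A fold change of at least 2 left 920, 346, 1108, 48, 30 and 731 genes in the 6 comparisons in the order above, 123 moved back and 41 shared. Without both libraries that lay apart, 330 genes differed for MT-Cd against Cd and 20 for MT-Cd against Cd+IAA, 1184 moved back and 269 were shared.

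Leaving out each library of a comparison in turn gave 4294 to 6240 genes for Cd against CK, 559 to 1430 for Cd+IAA against Cd, 6573 to 8813 for Cd+IAA against CK, 0 to 28 for MT-Cd against Cd, 10 to 280 for MT-Cd against Cd+IAA and 3203 to 6030 for MT-Cd against CK. It gave 185 to 714 moved back and 0 to 195 shared. The 195 came without Cd+IAA replicate 1, which is outside MT-Cd against Cd but part of the shared fit. That comparison then had at least 195 calls, above its range of 0 to 28. Called lists numbered 4 to 8 for Cd against CK, 5 to 7 for Cd+IAA against Cd, 5 to 9 for Cd+IAA against CK and 1 to 6 for MT-Cd against Cd.

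Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.561 to 0.344, above 0.1 in 3 of 18 pairs, and 3 of 12 libraries correlated best with their own number. With a replicate block limma called 1032 genes for Cd+IAA against Cd, 0 for MT-Cd against Cd (1999 at an unadjusted p under 0.05), 4 for MT-Cd against Cd+IAA and 0 shared.

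Camera at its preset correlation called 7, 5, 8 and 5 lists for Cd against CK, Cd+IAA against Cd, Cd+IAA against CK and MT-Cd against Cd. With an estimated correlation it called 0, 0, 0 and 0 (2, 2, 1 and 0 at an unadjusted p under 0.05). Fry, which asks whether a list's own genes move 1 way, called 14 lists for Cd against CK, 15 for Cd+IAA against CK and 0 for MT-Cd against Cd (3 at an unadjusted p under 0.05). It does not set a list against the other genes. Upward fry calls against CK can therefore come from the shift of all tested genes (median log2 fold change 0.22 in Cd and 0.254 in Cd+IAA). Vascular markers passed for Cd against CK (fry adjusted p = 0.000589), though their median lay 0.021 below that of all genes. Quantile normalization called 3 for Cd+IAA against CK, 2 of them among the 8 called in the main fit, and 1 for MT-Cd against Cd. Median-ratio scaling left 2 for MT-Cd against Cd, and leaving out both libraries that lay apart left 5 for Cd+IAA against CK. Fry gave the opposite direction for reactive oxygen scavenging (adjusted p = 0.651) and cell wall genes (0.544) for Cd against CK and for cell wall genes for Cd+IAA against CK (0.682). Photosystem genes turned downward for MT-Cd against Cd after quantile normalization (camera adjusted p = 0.81).

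Of 202 log2 fold changes of named genes 160 passed the threshold, and 43 of these lost it without at least 1 library. Signs turned for SNAT, ca2 and rbcS1 in the comparisons named here, in none of which they had passed in the main fit. SNAT against CK became -0.196 in Cd and -0.128 in Cd+IAA after quantile normalization, -0.232 and -0.226 after median-ratio scaling, and -0.016 to 0.046 in Cd with 1 library left out. For Cd+IAA against Cd it was -0.003 to 0.049 with 1 library left out and -0.003 without both libraries, and for MT-Cd against CK -0.103 to 0.012 with 1 left out. For MT-Cd against Cd, ca2 became 0.022 with library weights, -0.97 to 0.145 with 1 library left out and 0.088 without both libraries, and rbcS1 became -0.398 to 0.028 with 1 left out and 0.028 without both. For Cd+IAA against Cd, ca2 was -0.119 to 0.996 with 1 left out.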

Other observations

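Several further lists were measured under cadmium. Of 15 WRKY transcription factor genes 8 rose and 0 fell against CK, led by WRKY81 (log2 fold change 3.19 ± 0.50; 10 rose when adjusted over the list alone), while the list did not pass (camera adjusted p = 0.0578, and 0.00372 after median-ratio scaling, where it passed). Of 4 class III peroxidase genes 2 rose, CEVI-1 from 16.6 ± 1.28 to 177 ± 48.8 FPKM (SD, n = 3; 4 rose when adjusted over the list alone; camera adjusted p = 0.115, and 0.0401 after median-ratio scaling). Of 13 phosphate starvation genes 5 rose and 1 fell, 3 and 2 after median-ratio scaling, with PT1, a phosphate transporter gene, at 1.89 ± 0.38 (camera adjusted p = 0.653). Of 22 heat shock and chaperone genes 6 rose and 2 fell, 3 and 3 after median-ratio scaling (6 and 1 when adjusted over the list alone; camera adjusted p = 0.653), and BiP/grp78, an endoplasmic reticulum chaperone gene, rose by 1.08 ± 0.18. In the Cd+IAA to Cd comparison 6 chaperone genes rose and 1 fell (7 and 3 when adjusted over the list alone; camera adjusted p = 0.164), DNAJ by 1.31 ± 0.17.

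Markers of other cell types passed in few cases. For Cd against CK 1 of 7 trichome, 2 of 5 vascular and 2 of 10 epidermis and cuticle markers rose (camera adjusted p = 0.597, 0.689 and 0.766). After median-ratio scaling these lists had 0, 1 and 1 higher and 0, 1 and 1 lower. The guard cell list had 1 tested member, ca2, at 729 ± 508 FPKM in Cd and 3532 ± 338 in CK. A single gene cannot stand for a cell type, so its fall is not read as a change in guard cells. The carbon fixation list had 3, too few for camera, and none passed for Cd against CK. For the same comparison the remaining lists did not pass camera. Their genes higher and lower in Cd, with the counts after median-ratio scaling in brackets, were 9 and 3 (3 and 5) for Aux/IAA and GH3 genes (adjusted p = 0.278), 1 and 0 (1 and 0) for auxin synthesis (0.832), 6 and 3 (3 and 5; 6 and 2 when adjusted over the list alone) for auxin transport and response factors (0.355), 2 and 0 (1 and 0) for sulfate and glutathione synthesis (0.291), 0 and 0 (0 and 0) for chlorophyll breakdown (0.784), 2 and 1 (0 and 1; 1 and 0 over the list alone) for abscisic acid (0.355), 8 and 0 (3 and 1; 7 and 0 over the list alone) for phenylpropanoids (0.784), 6 and 0 (0 and 3; 0 and 0 over the list alone) for cell division (0.0953), 2 and 1 (0 and 1) for gibberellin (0.355) and 0 and 0 (0 and 2) for steroidal glycoalkaloids (0.155).

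Of the tests below, those of the FPKM sum without abundant genes, of the depth and of the cadmium response of Cd+IAA replicate 1, of a general fall of transcripts for chloroplast proteins, and of other splits were chosen after the results they bear on had been seen. The first pattern is the excess of higher calls under cadmium. A lower depth of the CK libraries, as the only source, would limit the excess to low genes. Of the calls with a mean of at least 20 FPKM 83.6% were higher in Cd, which argues against depth as the only source. It cannot set aside a part played by depth among low genes. A smaller share of FPKM in a few abundant genes was tested by 2 routes. After median-ratio scaling 50.3% of calls were higher, but that scaling centres the fold changes and so decides nothing. Dividing by the FPKM sum outside the 100 most abundant genes lowered the median log2 fold change from 0.22 to 0.096, with 73% of 4756 calls higher, which lies between the bounds set and leaves open how much of the shift is composition and how much a change in the leaf.

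The second pattern is that Cd+IAA replicate 1 lay apart from replicates 2 and 3. Its relative depth was above that of 4 libraries, which argues against low depth. Swapping its label with that of MT-Cd replicate 3 raised the mean residual variance to 1.159 times its value, which argues against that swap. Its difference from replicates 2 and 3 correlated across genes with the Cd to CK change at r = 0.46, consistent with a stronger cadmium response in that library as a hypothesis, and the like value for MT-Cd replicate 3 was 0.478. The labels give no batch, so a shared handling effect on both libraries stays open.

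The third pattern is the fall of both copper/zinc superoxide dismutase genes under cadmium, chosen after their values were seen. A copper shortage response, in which copper enzymes give way to iron ones, would lower CCS, the copper chaperone of these enzymes, and raise FESOD, the iron superoxide dismutase gene, and both were predicted before their values were seen. CCS fell, with a log2 fold change of -1.189 ± 0.174 (limma adjusted p = 0.000943). FESOD had -0.28 ± 0.235 (limma adjusted p = 0.359), so the predicted rise was not seen. It lay below 0 by more than 1 standard error, the bound set beforehand for an answer against an exchange of copper for iron enzymes. That bound was widened for a time once the value was known, and then restored. The libraries of Cd and CK overlapped and the test did not pass. The value therefore cannot be told from no change and decides nothing on that exchange. Of the other genes tied to copper, PETE had -0.976 and CCH 1.264, neither of which was predicted. A response limited to copper-dependent genes stays open. The 23 photosystem genes had a median log2 fold change of -0.562 (SD 0.522) and a lowest value of -1.907 ± 0.603. SODCP.2, the chloroplast form, fell further than each of them (-4.077 ± 0.414). That gene was picked for its large fall after the values were seen, so it was bound to lie low against such a list. The comparison therefore decides nothing on a general fall of transcripts for chloroplast proteins. SODCC.1, the cytosolic form, is not covered by that test.

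The covariance of the Cd to CK and Cd+IAA to Cd changes, -0.0627, was more negative than in each of 100 draws of unchanged groups (-0.0208 to -0.0163). The draws took each gene independently, while in the data the deviations of libraries of different groups correlated across genes at -0.561 to 0.519. The simulated range can therefore be too narrow, and the test does not set aside chance through the shared Cd libraries. Of the photosystem genes higher in Cd+IAA than in Cd, 0 stayed called after median-ratio scaling, a test that decides nothing because 2 were called to begin with.

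The 6 libraries of a comparison can be split into groups of 3 in 10 ways, too few for a share under 0.05. Each split was fitted with all 12 libraries, as the main counts were. The real split was the 1 with the most genes in each of the 6 comparisons. Every other split mixes the groups compared, which puts any real difference between them into the spread. Low counts in those splits are therefore no reference for unchanged groups. The real counts and the highest of the other splits were 6762 and 1 for Cd against CK, 1570 and 0 for Cd+IAA against Cd, 8832 and 0 for Cd+IAA against CK, 79 and 4 for MT-Cd against Cd, 91 and 12 for MT-Cd against Cd+IAA, and 6465 and 0 for MT-Cd against CK.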
